A study of Homo sapiens with 16 samples.

How the data were processed

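H295R is an established human adrenocortical carcinoma cell line that makes steroid hormones, aldosterone among them, and carries receptors for the peptide hormone angiotensin II. Total RNA of H295R cells kept for 3 h with 100 nM angiotensin II and total RNA of control cells were labelled with different dyes and hybridised together on glass slides spotted with cDNA clones, so that each array gave a ratio between both RNAs. The clone set was spread over 2 slide types, called slide a and slide b here after the sample titles. The 16 samples were 8 arrays of each type, numbered 16 to 23 in the titles. The labels name control RNA as channel 1 and angiotensin II RNA as channel 2 on all 16 arrays and give no dye per channel. The design text of the series speaks of 6 hybridisations with dye swap, while 8 arrays per slide type were analysed here.

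The deposited values were log ratios of both channels, 1 per spot and array. Per the series design text, the authors scanned the slides with a ScanArray instrument, quantified spots with QuantArray and normalised each slide with a rank-invariant method followed by loess regression. The base of the logarithm, the order of the channels within the deposited log ratio, the filters on spots and the software versions were not given in the sources used here. Array medians of the deposited log ratio lay between -0.012 and 0.00077 on slide a and between -0.021 and 0.0069 on slide b. Centring of this kind removes any shift shared by most genes, so each value is relative to the bulk of the spots on its array. Values are given below as deposited log ratios, and folds are given for both usual bases, 2 and 10. Spot intensities, backgrounds and flags were not used here, so the signal behind a ratio is unknown. The number of arrays limits the precision.

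Each table held 19200 spots with no missing value. Neighbouring spots form pairs of the same clone (0 pairs bore different names), and each pair was averaged, which left 9600 probes per slide type. A minimum of 6 arrays per probe was set and removed no probe. Gene names came from GEO's platform annotation: 7936 of the 19200 probes bore 1 gene symbol, 329 bore several and 10935 bore none, and only probes with 1 symbol were named. Entrez identifiers of 3932 of 3936 such probes on slide a and of 3996 of 4000 on slide b matched the human RefSeq gene table (assembly GRCh38.p14), which changed 0 symbols. The named probes covered 6261 genes, 549 of them on both slide types. No genome build is stated for the arrays, so no coordinates are given.

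Ratios were read as angiotensin II over control, from the channel order in the labels. This direction is likely but not settled, because arrays with odd and even numbers correlated below 0, and counts are therefore also given with the sign of the odd-numbered arrays turned. A common reversal of all arrays would exchange higher and lower. Each slide type was tested alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept against 0, two-sided), with Benjamini-Hochberg adjustment over its 9600 probes and a threshold of 0.05. The design assumed log2 values; since the base was not stated, the same test was run on the values as deposited. The labels do not say that the arrays stem from separate cultures, so p-values measure the spread between arrays, which may be technical. No pair of arrays was a copy of another: the highest correlation was 0.453 on slide a and 0.471 on slide b.

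The following choices were made before the data were examined. Gene lists, 16 in number, covered steroid synthesis, cholesterol synthesis and uptake, immediate early transcription factors, NR4A and adrenal nuclear factors, signalling feedback, cytoskeleton and adhesion, matricellular and secreted factors, cell cycle, unfolded protein and heat shock, ion transport and membrane potential, ribosomal proteins, respiratory chain, housekeeping references, and markers of chromaffin, fibroblast and endothelial, and blood cells. Lists with at least 5 measured genes on a slide type were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. A gene counted as risen or fallen if 1 of its probes passed in that direction and none in the other. The rule for named genes took the largest changes among probes past the threshold. Where fewer than 5 probes passed in a direction, it took the 5 probes with 1 symbol and the smallest p in that direction over both slide types. It also took STAR, CYP11B2, CYP11B1, AGTR1, NR4A1, NR4A2 and NR4A3 wherever measured. The single example given for each list below is its probe with the smallest p and was chosen after its values were seen.

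Means of single lists over 8 arrays were tested with exact sign-flip tests over all 256 sign patterns, whose smallest possible two-sided p is 0.00781. These tests, like the limma test, took the arrays as independent. The physical layout was inferred from the order of spots. Correlations between spots of the same array peaked at a distance of 24 spots (mean 0.369 on slide a) and again at 2400 (0.264, against 0.0896 at 1200), which was read as 32 subgrids of 25 rows by 24 spots. A position trend, the running median over 11 by 11 spots of that layout, was subtracted from each array as an alternative chosen after seeing the data.

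The probe and list tests were tested on simulated data made from the arrays' own residuals. Each probe's mean was removed and replaced by an independent random one. Parts of the means that probes share, such as a position trend, were thereby left out. The false calls and the rates for lists that were not shifted hold for such independent means only. For limma and SAM, 50 probes at each of the sizes 0.1, 0.2, 0.4 and 0.8 were shifted together among 9600 and tested at once. The larger shifts eased the threshold for the smaller ones. The rates at 0.1 and 0.2 therefore hold only where larger changes are also present, and recovery of such shifts alone was not tested. The limma test recovered 8% of probes shifted by 0.1, 62% at 0.2 and 100% at 0.4 and 0.8 on slide a, with 2 false calls. On slide b it recovered 8%, 84%, 100% and 100% at the same sizes, with 2 false calls. With a term for odd and even numbers, limma recovered 86% at 0.2 on slide a (11 false calls) and 92% on slide b (8 false calls). SAM recovered 12%, 84%, 100% and 100% on slide a with 5 false calls, and 14%, 96%, 100% and 100% on slide b with 4 false calls. A list of 9 genes shifted by 0.05 gave a camera p under 0.05 in 48 of 50 draws on slide a and in all 50 on slide b, against 3 and 2 of 50 draws for lists that were not shifted. For the same shift fry gave a p under 0.05 in 41 and 45 of 50 draws and the sign-flip test in 40 and 43, against 2 and 3 draws (fry) and 3 and 1 (sign-flip) for lists that were not shifted. These lists held random genes, whereas the signalling feedback genes on slide a had an estimated correlation of 0.262. The permutation test of clone pairs was tested on random values drawn without any effect of position. It gave a p under 0.05 in 93% of 200 draws within a slide type and in 83% between slide types where clones of a gene shared 10% of the variance, and in 4% and 3.5% where they shared none. The alternatives covered the minimum number of arrays, 3 scalings between arrays, robust variances, array weights, single spots, gene averages, joint adjustment, slide lots as a random block, averages of consecutive arrays, a minimum fold of 1.2, SAM (the test named by the submitters) and leaving out each array. Arrays 22 and 23, which had the widest values on slide b, were also left out together after seeing the data.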

Results

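The series asked which transcripts of H295R adrenocortical cells differ 3 h after addition of 100 nM angiotensin II, the peptide that drives aldosterone secretion in the adrenal cortex. Log ratios of treated over control RNA were analysed on 8 arrays of slide a and 8 arrays of slide b, each with 9600 probes. Values are deposited log ratios whose base is not stated, and their direction, taken from the channel order in the labels, is not settled. The SD of the spots of an array ran from 0.095 to 0.21 on slide a and from 0.099 to 0.18 on slide b. The median standard error of a probe mean was 0.042 on slide a and 0.038 on slide b.

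On slide a, the genes furthest above 0 relative to their error were TENT5A, a terminal nucleotidyltransferase, and LONRF2, a RING finger protein. TENT5A had a mean log ratio of 0.14 ± 0.12 (SD, n = 8), above 0 on 8 of 8 arrays, which is 1.11-fold if the base is 2 and 1.40-fold if it is 10, while its other clones averaged -0.038 (slide a) and -0.064 (slide b). With the sign of the odd-numbered arrays turned it averaged 0.055 (limma adjusted p 0.432). LONRF2 averaged 0.19 ± 0.20 and was above 0 on 7 of 8 arrays. PLEK, a protein kinase C substrate, averaged -0.12 ± 0.10, PPP1R12B, a regulatory subunit of myosin phosphatase, averaged -0.12 ± 0.11, and ANKH, a pyrophosphate transporter, averaged -0.099 ± 0.064, each below 0 on 8 of 8 arrays. Other clones of ANKH averaged 0.0056 on slide a and 0.0067 on slide b. STAR, which carries cholesterol into mitochondria for steroid synthesis, averaged 0.080 ± 0.10 and was above 0 on 7 of 8 arrays (95% interval -0.0037 to 0.16). Its value on array 22 was -0.14, and its mean was 0.11 without that array and 0.067 without array 21. AGTR1, the receptor for angiotensin II, averaged -0.073 ± 0.12 and was below 0 on 5 of 8 arrays. None of these genes passed the test. limma called 0 probes higher and 0 lower (smallest adjusted p 0.999), and at an unadjusted p under 0.05 there were 66 probes above 0 and 90 below 0 where chance gives 480 in all. On both slide types limma took the arrays as independent, although odd- and even-numbered arrays correlated below 0, so its p-values may be too large. SAM also called 0 probes in either direction.

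On slide b, MBNL2, an RNA-binding regulator of splicing, and NR4A3, an orphan nuclear receptor of the NR4A family, lay furthest above 0. MBNL2 averaged 0.17 ± 0.10 (SD, n = 8) and was above 0 on 8 of 8 arrays, which is 1.12-fold at base 2 and 1.48-fold at base 10, while its other clones averaged from -0.023 (slide a) to 0.069 (slide b). NR4A3 at spot 16329 averaged 0.23 ± 0.22 and was above 0 on 6 of 8 arrays, 1.17-fold at base 2 and 1.70-fold at base 10. The remaining clones that bear the name NR4A3 averaged 0.0016 ± 0.12 at spot 15127, -0.053 ± 0.073 at spot 16927 and -0.11 ± 0.13 at spot 18129. DENND1B, an exchange factor for Rab GTPases, averaged 0.11 ± 0.062 and was above 0 on 8 of 8 arrays. Below 0 lay SCN4B, a sodium channel subunit, with -0.11 ± 0.11 (6 of 8 arrays below 0, -0.013 on slide a), and ARHGAP20 with -0.087 ± 0.066 (7 of 8 below 0). Over both slide types, 21 probes below 0 that bore no symbol or several had a smaller limma p than ARHGAP20. Above 0, 3 such probes had a smaller p than LONRF2. None of these genes passed the limma test, which called 0 probes higher and 0 lower (smallest adjusted p 1.00), with 42 probes above 0 and 54 below 0 at an unadjusted p under 0.05 against 480 by chance. SAM called 2 probes higher, NR4A3 at spot 16329 and MBNL2, and 0 lower. CYP11B2, CYP11B1, NR4A1 and NR4A2 had 0 named probes on either slide type.

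**Figure D1:**
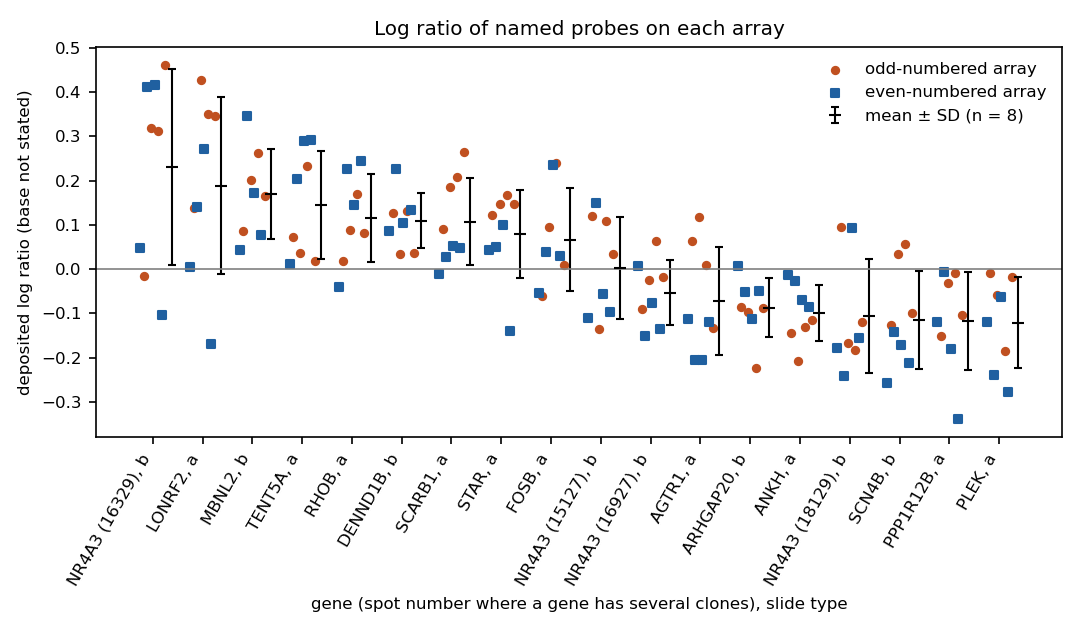
Deposited log ratio (y axis, base not stated) of named probes (x axis, with slide type a or b) on each of 8 arrays, odd-numbered arrays as circles and even-numbered ones as squares, with the mean and SD in black. NR4A3 at spot 16329 has the highest mean, 0.23, and the other NR4A3 clones lie at 0.0016, -0.053 and -0.11.

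The signalling feedback list, which holds RGS proteins, MAP kinase phosphatases, Sprouty proteins and similar early response genes, lay above the other genes of slide a by camera, a test that compares a list with the remaining genes. The mean of its 9 genes there was 0.042 ± 0.070 (SD over 8 arrays), above 0 on 7 of 8 arrays, and camera gave an adjusted p of 0.00432, which was lost with an estimated correlation (adjusted p 0.378). Tests of the list against 0 did not pass (fry p 0.127, adjusted p 0.447; exact sign-flip p of the mean 0.133). RHOB, a small GTPase, averaged 0.12, SPRED2 0.065, DUSP1, a MAP kinase phosphatase, 0.061 and SOCS3 0.048, and of the 9 genes 7 lay above 0. Single arrays weighed on these means: SPRED2 reached 0.36 and DUSP1 0.25 on array 22, and SOCS3 0.21 on array 18. The adjusted p of camera was 0.192 without array 18, where the mean fell to 0.024, 0.0807 without array 22, and 0.0672 without RHOB, where the other 8 genes averaged 0.033. On slide b the 13 genes of the list averaged 0.012 ± 0.044 (camera adjusted p 0.729). The list mean was 0.11 on array 23 there, and without that array the direction turned downward (camera adjusted p 0.755, fry adjusted p 0.902). Over both slide types, 0 of its 21 measured genes rose, 0 fell, and 0 of 23 probes passed when adjusted over the list alone.

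Genes of steroid synthesis and of its cholesterol supply did not pass the test. Of 5 measured steroid synthesis genes 0 rose and 0 fell, their means ran from -0.073 (AGTR1) to 0.080 (STAR), and 0 probes passed when adjusted over the list alone. Of 12 genes of cholesterol synthesis and uptake 0 rose and 0 fell, 7 lay above 0 and 5 below, and 0 probes passed when adjusted over the list alone. On slide b the 9 genes of the cholesterol list averaged 0.0011 (camera adjusted p 0.786). SCARB1, the receptor for high-density lipoprotein, averaged 0.11 ± 0.099 on slide a and was above 0 on 7 of 8 arrays (unadjusted p 0.0144), while its clone on slide b averaged 0.00034 and was above 0 on 4 of 8.

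Of 15 immediate early transcription factors 0 rose and 0 fell, and 0 probes passed when adjusted over the list alone. FOSB, a component of AP-1, averaged 0.067 ± 0.12 on slide a (0.042 without array 21) and was above 0 on 6 of 8 arrays, and its other clones averaged 0.032 on slide a and -0.021 on slide b. On slide b the 9 genes of this list averaged -0.015 ± 0.018, below 0 on 7 of 8 arrays, and camera did not pass after adjustment (p 0.0439, adjusted p 0.307). Of 5 NR4A and adrenal nuclear factors 0 rose and 0 fell over all probes tested, and 1 of 8 probes, NR4A3 at spot 16329, passed when adjusted over the list alone (adjusted p 0.0157). That adjustment did not cover the other lists. Another clone of NR4A3, at spot 18129, lay below 0 (mean -0.11, limma unadjusted p 0.0229).

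In the other lists 0 genes rose, 0 fell and 0 probes passed when adjusted over the list alone. Among 13 genes of ion transport and membrane potential, KCNK3, a potassium channel, averaged -0.071 ± 0.094 on slide a and 0.044 ± 0.066 on slide b. Among 10 respiratory chain genes, of which 7 lay below 0, SDHC averaged -0.066 ± 0.049. Among 9 genes of cytoskeleton and adhesion, MYH9, a myosin heavy chain, averaged 0.036 ± 0.10 on slide b (0.015 without array 22, 0.065 without array 17), with other clones at 0.018 on slide b and -0.0062 on slide a. CCN1, a matricellular protein, averaged 0.024 ± 0.054 (0.014 without array 17, 0.037 without array 16) among 6 secreted factors. CDKN1A, a cell cycle inhibitor, averaged 0.050 ± 0.15 on slide a (0.014 without array 22, 0.078 without array 17) and -0.0066 ± 0.097 on slide b, below 0 there on 6 of 8 arrays, among 5 cell cycle genes. ATF6, a sensor of unfolded protein, averaged 0.047 ± 0.19 among 5 genes of its list (-0.0069 without array 21; other clones -0.029, 0.00070 and 0.035), and RPL41 averaged 0.043 ± 0.17 among 5 ribosomal protein genes (-0.0020 without array 23; other clones 0.028 and 0.012). TFRC, 1 of 2 housekeeping references, averaged 0.054 ± 0.11 (0.021 without array 18). Among 5 fibroblast and endothelial markers, PECAM1 averaged 0.058 ± 0.053 on slide b and 0.021 ± 0.14 on slide a, and 0 chromaffin and 0 blood cell markers were measured. Lists were large enough for camera in 4 cases on slide a and in 7 on slide b, and apart from the signalling feedback list on slide a and the immediate early list on slide b their adjusted p ran from 0.434 to 0.811.

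Arrays with odd and even numbers ran in opposite directions. On slide a, the 16 pairs of an odd- and an even-numbered array had a median correlation of -0.294 over probes, with 8 pairs below -0.3, while the 12 pairs of the same kind had a median of 0.305. On slide b the medians were -0.243, with 6 pairs below -0.3, and 0.256. Probes are not independent replicates, so no p is given for these correlations.

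**Figure D2:**
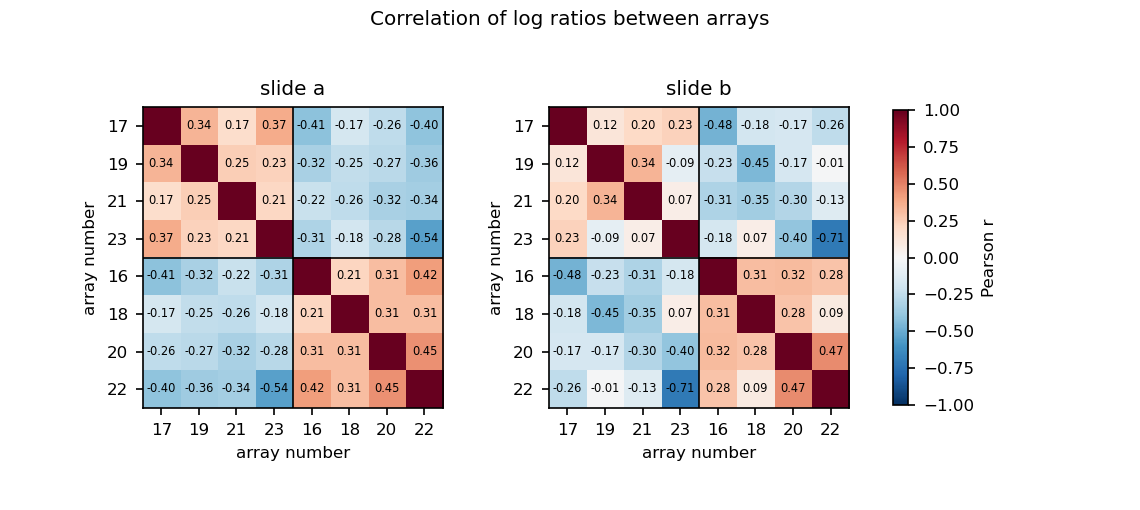
Pearson correlation of log ratios over 9600 probes between the arrays of slide a (left) and slide b (right), with array numbers on both axes, odd numbers before even ones and lines between them. Pairs of an odd and an even number range from -0.542 to -0.173 on slide a and from -0.706 to 0.0695 on slide b.

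With the sign of the odd-numbered arrays turned, a reading chosen after seeing the data, limma called 883 probes above 0 and 928 below 0 on slide a, and 464 and 442 on slide b. Of the probes with 1 symbol, 759 of 3936 on slide a and 372 of 4000 on slide b passed in this reading. Of 23 signalling feedback probes 3 passed above 0 and 0 below, and of 23 immediate early probes 3 and 1. In all, 16 probes of the fixed lists passed, 9 above 0 and 7 below. Whether list probes passed more often than other named probes was not tested. Among the list probes above 0 were FDX1, the electron donor of mitochondrial steroid hydroxylases, with 0.13 ± 0.081 (SD, n = 8, adjusted p 0.0239), EGR3 with 0.18 ± 0.15, DUSP10 with 0.15 ± 0.11, and DUSP1 on slide b with 0.11 ± 0.050. Among those below 0, VIM, the intermediate filament protein vimentin, averaged -0.22 ± 0.17 and MVD, an enzyme of cholesterol synthesis, averaged -0.19 ± 0.15. Of the 16 list probes, 2, MVD and VIM, also passed once the position trend was removed. With the position trend removed the calls were 23 above 0 and 24 below 0 on slide a, and 173 and 211 on slide b. Probes past the threshold in both ways, in the same direction, numbered 31 on slide a and 191 on slide b. Named genes among these with the same sign on all 8 turned arrays were ranked by their mean with the position trend removed. The 3 furthest below 0 were CIT, a kinase of cell division, with -0.27 ± 0.075, HIPK1 with -0.19 ± 0.083, the zinc exporter SLC30A1 with -0.17 ± 0.14, and the 3 furthest above 0 were POU2AF3 with 0.19 ± 0.11, DHRS7B with 0.17 ± 0.14 and the protease PRSS8 with 0.16 ± 0.11. Other clones of CIT, SLC30A1 and PRSS8 averaged -0.11, -0.050 and 0.022 in the same way. STAR, NR4A3 at spot 16329 and MBNL2 averaged -0.066, -0.038 and -0.0097 with the odd-numbered arrays turned and did not pass. TENT5A, DENND1B, PLEK, PPP1R12B and SCN4B kept their sign, at 0.055, 0.028, -0.054, -0.044 and -0.081, and did not pass either.

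**Figure D3:**
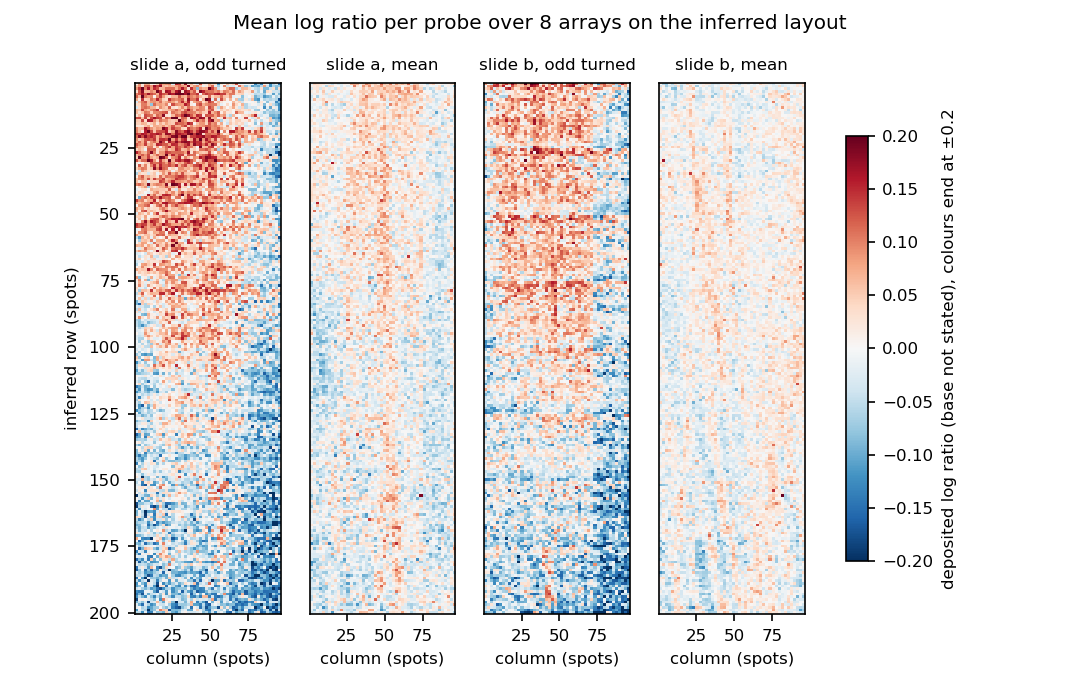
Mean log ratio per probe over 8 arrays (colour, base not stated) at its row and column on the inferred spot layout, for slides a and b, with the odd-numbered arrays turned and as deposited. With the odd-numbered arrays turned, 52.0% (slide a) and 40.6% (slide b) of the variance lay between the 32 subgrids, and for the mean as deposited 21.3% (slide a) and 12% (slide b).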

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

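The tests of explanations below were chosen after the results were seen, except the test of single members of the signalling feedback list, and the search for outlying arrays was fixed before the data were examined.

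Arrays with odd and even numbers ran in opposite directions, with a median correlation of -0.273 over both slide types. A trend over the slide surface of the scale that the running median removes is argued against as the whole cause. Once that trend was removed, a correlation of -0.152 remained. Neighbouring probes then still correlated at 0.059 (array 16) to 0.226 (array 23) on slide a. On slide b they correlated at 0.068 (array 16) to 0.278 (array 23). A finer trend as the whole cause therefore stays open. A trend over the slide surface may be part of the cause, since at least 40.6% of the variance of the odd-even component lay between inferred subgrids. In 1000 shuffles of the probes the share was at most 0.643%. The shuffles add no support, because the subgrids were inferred from the same arrays. Neighbouring probes correlated there, so shuffled probes were bound to give a lower share. A response to angiotensin II that was deposited without turning the dye-swapped arrays cannot be told apart from a dye bias of the probes, because dyes per channel are not given and clones of the same gene gave mixed results. Position removed, the odd-even component of clone pairs correlated at 0.0060 between slide types (790 pairs, one-sided permutation p 0.431) and at 0.088 within a slide type (864 pairs, p 0.0046), over 10000 permutations (adjusted p 0.492 and 0.0184 among 8 such correlations). Clones paired within a slide type lay at least 100 spots apart. As deposited, spots 600 apart still correlated at 0.145 on slide a and 0.164 on slide b. A remaining effect of position on the pairs within a slide type therefore stays open.

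Of the 4 clones named NR4A3, the clone at spot 16329 averaged 0.23 and exceeded the mean of the other 3 clones by 0.28 ± 0.22 (SD, n = 8, higher on 7 of 8 arrays), for which no p is given because the clone was picked on the same arrays. A position trend of the scale that the running median removes is argued against by its mean with that trend removed, 0.22. A dye bias stays open: the means over even- and odd-numbered arrays, 0.19 and 0.27, have the same sign, which a dye bias also gives if dye-swapped arrays were deposited without turning. Whether the clones measure several transcripts could not be settled: the clone that was highest on the even-numbered arrays exceeded the other 3 on the 4 odd-numbered arrays by 2.39 standard errors. A response of the NR4A3 gene to angiotensin II therefore stays open, and the other 3 clones, at 0.0016, -0.053 and -0.11, do not show it.

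On slide a the signalling feedback genes averaged 0.042 and lay above the other genes by camera at the preset correlation, a call that was lost with an estimated one (0.262, adjusted p 0.378). A position trend as the whole cause stays open. With the trend removed the mean was 0.035 ± 0.048 (SD, n = 8, sign-flip p 0.0703), against 0.042 as deposited. Camera then passed at the preset correlation (p 0.00504, adjusted p 0.0202) but not with an estimated one (p 0.0904), nor did fry (p 0.0902). The tests that did not pass had not passed before removal either (camera with an estimated correlation p 0.0944, fry p 0.127), so they cannot decide the question. Whether RHOB alone made the call stays open: without it the mean went from 0.042 ± 0.070 (SD, n = 8) to 0.033 ± 0.070, above 0 on 5 of 8 arrays (sign-flip p 0.320), and the camera p was 0.0168, under the bound of 0.05 set beforehand. That bound ignored adjustment (adjusted p 0.0672) and the correlation of the genes (p 0.163 with an estimated one). A response of these genes to angiotensin II may account for the position of the list but cannot be told apart from chance variation between arrays, because the exact two-sided sign-flip p of the list mean was 0.133 (adjusted p 0.602 over 11 list means) and the mean on slide b was 0.012 with 4 of 8 arrays above 0. Without array 23 the list on slide b lay below 0 by fry (adjusted p 0.902).

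Other sign splits of the 8 arrays say nothing about chance for the counts of changed probes, because with a real count of 0 each split gives at least as many (100 of 100 on slide a and 100 of 100 on slide b, the real one included). The highest other count was 1811 on slide a and 906 on slide b, both from the split that turns the odd-numbered arrays, which points to a structure of the arrays. Only 3 splits on slide a and 1 on slide b called any probe.

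An array stood apart from the other 7 in 6 of 46 groups of 8 arrays, where chance gives about 2.3. The log ratio of STAR on array 22 of slide a was -0.14, and all other arrays lay above 0. TFRC had a log ratio of 0.29 on array 18 of slide a. The correlation between neighbouring probes was 0.601 on array 22 of slide a. The median of array 23 of slide b was -0.021. On array 23, the cholesterol synthesis and uptake list averaged 0.073 on slide a, and the signalling feedback list averaged 0.11 on slide b.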

How the results depend on the processing

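The choice to turn the odd-numbered arrays, to remove the position trend, to add a term for odd and even numbers, to leave out arrays 22 and 23 and to set a minimum fold at base 10 was made after seeing the data; the other settings were planned. Both RNAs were compared within each array, so no groups of samples were paired by number. Slide lots as a random block and averages of consecutive arrays, which were run, each gave 0 calls on both slide types. They were not separate checks: lots and consecutive pairs matched on slide b and differed on slide a only for arrays 22 and 23. The correlation within lots was -0.292 on slide a and -0.559 on slide b. With lots as a block the smallest limma adjusted p was 0.994 on slide a and 0.138 on slide b. Other minimum numbers of arrays changed nothing, since no value was missing.

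Counts of 0 higher and 0 lower probes held on both slide types under every setting tried that kept the direction of the arrays, except SAM, which called 2 probes higher on slide b. The range over arrays left out in turn was 0 to 0. With the odd-numbered arrays turned, the counts were 883 higher and 928 lower on slide a and 464 and 442 on slide b, and with the position trend removed as well 23 and 24 on slide a and 173 and 211 on slide b; the cause was not tested beyond the splits and position tests given with the odd-even pattern.

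The number of lists past the threshold, 1, ran from 0 to 1 over arrays left out. It was 0 with an estimated correlation, with fry, with both slide types stacked, without arrays 22 and 23 and with the odd-numbered arrays turned. The mean of the signalling feedback list on slide a stayed at 0.042 with an estimated correlation and with fry, where adjusted p rose to 0.378 and 0.447. It was 0.024 with both slide types stacked (adjusted p 0.152) and 0.034 without arrays 22 and 23 (0.0602). With the odd-numbered arrays turned it was 0.044 (0.264), and with the position trend removed as well 0.018 (0.631). In that last setting the immediate early list passed by camera on slide a, upward (adjusted p 0.0243), but not on slide b (0.960). By fry, the same list passed upward on slide a (adjusted p 0.0212). The cholesterol synthesis and uptake list (0.0161) and the ion transport list (0.0119) passed downward there. On slide b the smallest fry adjusted p was 0.130. Over arrays left out the mean of the signalling feedback list on slide a ran from 0.024 (without array 18) to 0.054. The cause was not tested.

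Of 27 named probes, 3 changed sign in 7 of 432 values that kept the direction of the arrays, and 0 passed. NR4A3 at spot 15127 moved to -0.015, -0.019, -0.014 and -0.0032 without arrays 17, 18, 21 and 23, ATF6 to -0.0069 without array 21, and RPL41 to -0.0020 without array 23 and -0.029 without arrays 22 and 23. Over arrays left out, these ran from -0.019 to 0.021, from -0.0069 to 0.083 and from -0.0020 to 0.081. In all, 22 of 216 values with an array left out moved by over 1.5 times, in 8 probes, none of them called. The other 5 probes ran from 0.014 (without array 22) to 0.078 (without array 17) for CDKN1A, from 0.021 (without array 18) to 0.072 for TFRC, from 0.015 (without array 22) to 0.065 (without array 17) for MYH9, from 0.014 (without array 17) to 0.037 (without array 16) for CCN1, and from 0.042 (without array 21; 0.043 without array 20) to 0.085 for FOSB. With the odd-numbered arrays turned, 25 of 54 values changed sign. As deposited these were LONRF2 -0.13, ANKH 0.050, STAR -0.066, SCARB1 -0.079, FOSB -0.0041, MBNL2 -0.0097, ARHGAP20 0.036, CCN1 -0.035, ATF6 -0.0060, RPL41 -0.044 and NR4A3 -0.038 (spot 16329) and -0.030 (spot 15127). With the position trend removed these were LONRF2 -0.050, PLEK 0.056, PPP1R12B 0.021, ANKH 0.075, STAR -0.091, SCARB1 -0.026, CDKN1A -0.0093, SDHC 0.030, MBNL2 -0.0095, ARHGAP20 0.050, CCN1 -0.013 and NR4A3 -0.0069 (spot 15127) and 0.018 (spot 18129). CDKN1A (0.12) passed with the odd-numbered arrays turned, and PECAM1 (0.090) with the position trend removed as well. Signal over background, which limits single spots, was not used here.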

Other observations

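Of the values in this part, the correlation between averages of consecutive arrays, the counts with consecutive arrays averaged and the list tests over both slide types were planned before their results were seen, and the others were looked at after the counts were known.

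Over 790 pairs of clones of the same gene on different slide types, the mean log ratio correlated at 0.0093 (one-sided permutation p 0.394). KCNK3 lay below 0 on 6 of 8 arrays of slide a and above 0 on 6 of 8 arrays of slide b. DUSP1, a phosphatase that ends MAP kinase signalling, averaged 0.061 on slide a and 0.0035 on slide b. With genes averaged over both slide types, the respiratory chain list lay below the other genes by camera (p 0.0372) and did not pass after adjustment (adjusted p 0.242), and fry, which tests against 0, gave a p of 0.149. The signalling feedback list then lay above the other genes with a camera adjusted p of 0.152 and a fry p of 0.102.

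Fewer probes than chance gives had a small p. On slide a 156 probes had an unadjusted p under 0.05 and on slide b 96, against 480 by chance. The test took the arrays as independent, although odd- and even-numbered arrays correlated below 0, so its p-values may be too large. With a term for odd and even numbers the counts were 410 on slide a and 164 on slide b. The same sign on all 8 arrays occurred for 0.344% of probes on slide a and 0.271% on slide b, against 0.781% by chance. With consecutive arrays averaged, 4 values per probe, 673 and 575 probes had an unadjusted p under 0.05 and 0 passed after adjustment (smallest adjusted p 0.152 and 0.377).

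The hypothesis that averages of consecutive arrays, each of an odd and an even number, share a response over probes was tested on values with the position trend removed. The mean correlation between the 4 averages was 0.036 on slide a and 0.049 on slide b, while the differences within the same pairs of arrays correlated at 0.225 and 0.256. The test left the hypothesis open, because the averages correlated above 0 but less than the differences.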
